A study of Mus musculus with 18 samples.

How the data were processed

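RNA of mouse trophoblast stem cells was measured on 18 Affymetrix mouse genome arrays, 3 for each of 6 groups: control (WT) and Lsd1-deleted (KO) cells at 0, 2 and 4 days of differentiation. Per the labels, the cells came from a conditional Lsd1 mouse line of mixed strain, deletion was induced 8 days before RNA collection with 0.2 µM 4-hydroxytamoxifen, RNA was isolated with Trizol, and biotin-labelled cRNA was hybridised. The deposited table gives 1 intensity per probe set and array, which the authors made with RMA per the submitters' processing notes. The RMA software and version are not given in the sources used here. The values were on a linear scale, so their log2 was taken here. Array median intensities ran from 55.8 to 58.8, and no array was left out. The groups were taken from the sample labels, and the replicates are called biological there. The array descriptions number the replicates from 1 to 3 in 5 groups, but end in 1 for all 3 KO arrays of d4, and the meaning is not given in the sources used here. These arrays were used as their titles label them. Arrays have no read depth, so precision depended on the 3 arrays per group and on 12 residual degrees of freedom.

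Of 45101 probe sets, 64 were Affymetrix controls. The platform annotation gave 1 gene symbol for 34958 probe sets, several for 932 and none for 9211, and only the first kind was used. Symbols were compared by gene number with a RefSeq gene table of assembly GRCm38.p6, used for names only: 34754 probe sets matched and 0 symbols changed. Of the 18194 genes left, 9012 had more than 1 probe set, and each was represented by the probe set with the highest mean over all arrays. Genes without a probe set of 1 symbol, such as Gcm1 and Prl3d1, were not analysed here. Affymetrix control probe sets were not removed by name here, so any with 1 gene symbol was treated like other probe sets. They were removed where all probe sets were tested singly.

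All 18 arrays entered 1 fit with limma 3.58.1 in R 4.3.3 (lmFit, eBayes) with a mean per group and no block. There were 9 contrasts: KO against WT on each day, d2 and d4 against d0 in each genotype, and the interactions at d2 and d4, which compare the KO-WT difference on that day with that at d0. Genes passed at a Benjamini-Hochberg adjusted p under 0.05, adjusted over the genes of each contrast. Standard errors are the moderated ones of that fit, with 1 spread per gene shared by all groups. No fold minimum was set, apart from the counts at 2-fold.

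The genes to be named were fixed by rule before the values were seen. For KO against WT on each day, these were the 8 largest rises and 8 largest falls among passing genes whose groups did not overlap. The rule took 6 and 6 for WT d4, 4 and 4 for WT d2 and KO d4, none for KO d2, the 4 most positive and 4 most negative passing interactions, and up to 4 members of each list with the largest change. Kdm1a, Ovol2, Cdx2, Eomes, Tpbpa and Hand1 were always named.

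A set of 25 gene lists with 383 genes, 351 of them measured, was written before the values were seen. They cover trophoblast stem cell, FGF/ERK response, trophoblast giant cell, spongiotrophoblast and glycogen cell, syncytiotrophoblast and labyrinth, mesenchymal and migration, epithelial, mitosis, DNA replication, p53 target, CoREST complex, REST-bound neuronal, germline, two-cell stage, interferon response, hypoxia and glycolysis, integrated stress response, cholesterol synthesis, lysosome and RNA handling stress genes. The other 5 hold genes of fibroblast, endoderm, pluripotent, macrophage and endothelial cells. Of their genes, 2 were found under a newer symbol. Members with values near or under the lower quartiles of the arrays were kept. Medians and counts of some lists, such as germline genes, thus partly rest on low values. Each list was tested in each contrast with limma camera at the preset correlation of 0.01, adjusted over all 225 tests. Beside it stood camera with an estimated correlation, the self-contained test fry, the number of members passing over all genes, and the number passing when adjusted over the list alone.

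Overlaps of the KO effects between days were counted per direction beside the number expected from independent calls. Correlations across genes between the KO-WT difference and the WT course were set beside 100 draws of unchanged groups that shared the same control arrays. Labels were also regrouped. For each pair of groups, genotype or day labels were regrouped in all 10 splits of 6 arrays into 3 and 3. For the interactions, genotype labels were regrouped in 100 relabellings within each day.

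The fit was tested on simulated data with the design and 18194 genes of the arrays and 1 pooled spread per gene. In these, 50 genes were changed at each fold size. At 1.25-, 1.5-, 2- and 4-fold it recovered 14, 70, 94 and 100% for KO against WT at d0, 20, 82, 94 and 98% at d2, 30, 82, 98 and 100% at d4, 16, 88, 94 and 100% for WT d4, and 4, 56, 92 and 98% for the interaction at d4. False calls made up 3.77, 5.88, 3.53, 4.71 and 3.62% of the calls. Lists with 15 genes planted at 1.5-fold were called, and unchanged lists gave camera p from 0.107 to 0.957. The noise was independent between genes and equally wide in all groups. The wider spread and shared deviation of the d2 arrays, and correlation between genes, were thus not simulated. The values for d2 and for lists therefore describe simpler data than the arrays.

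The alternatives tried were quantile normalization on top of the deposited values, arrays centred on their medians, the mean over a gene's probe sets, all probe sets tested singly, only genes above the median level, an intensity trend in eBayes, array weights, the replicate number as a block, only the arrays compared, a 2-fold minimum, and each array left out in turn. Centring used the median of each array over the 18194 genes (log2 6.81 to 7.06). It did not use the median over all probe sets, which differed little between arrays (intensity 55.8 to 58.8). Leaving out the 2 arrays of d2 that stood apart, and all arrays of d2, was added after seeing the data, as was the selection of genes that passed in the d4 minus d0 change of either genotype. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3.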

Results

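The data held 18 Affymetrix arrays of mouse trophoblast stem cells, 3 for each of 6 groups. Cells with an induced deletion of Lsd1, the histone demethylase encoded by Kdm1a (KO), and control cells (WT) were collected undifferentiated (d0) and after 2 and 4 days without FGF4, heparin and conditioned medium (d2, d4). The 3 arrays per group are biological replicates per the labels, but every culture came from 1 conditional mouse line. The p-values therefore measured the spread between cultures of that line, and part of that spread may have been technical. Precision was limited by the number of arrays, and 18194 genes were tested in 1 limma fit. Per the labels, the deletion had been induced 8 days before RNA collection with 0.2 µM 4-hydroxytamoxifen. The labels did not state whether the control cells received the drug, so the effects of deletion and drug could not be separated.

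Day of differentiation and genotype both separated the arrays. The first component of a principal component analysis held 51.7% of the variance, the second 25.1% and the third 12.1%. At d2, WT replicate 3 and KO replicate 2 stood apart from the other 4 arrays of that day, and their deviations from their group means correlated across genes (r = 0.874). The median gene SD between replicates was 0.147 in WT and 0.135 in KO cells at d2, against 0.0763 to 0.0891 in the other 4 groups. The fit pooled 1 spread per gene over all groups. For a typical gene, SEs and p-values of comparisons with d2 were thus likely too small. Those of comparisons without d2 were likely too large.

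**Figure D1:**
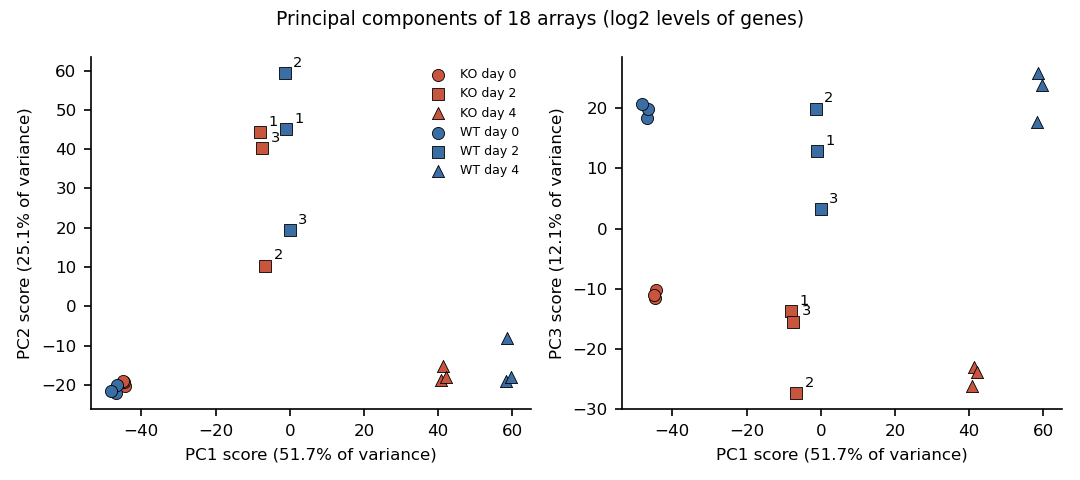
First 2 principal components of the 18 arrays over 18194 genes, with component 1 (51.7% of variance) on the horizontal and component 2 (25.1%) on the vertical axis; each point is 1 array. WT replicate 3 and KO replicate 2 of d2 lay low on component 2.

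Kdm1a RNA was lower in all KO arrays than in all WT arrays of the same day. Mean log2 intensity ± SD (n = 3) was 11.13 ± 0.08 in WT and 7.70 ± 0.16 in KO cells at d0. It was 11.18 ± 0.10 and 7.96 ± 0.24 at d2, and 10.62 ± 0.06 and 4.76 ± 0.40 at d4. KO cells held 10.7-fold less at d0 (log2 -3.42 ± 0.15 SE, adjusted p = 1.96e-10). They held 9.32-fold less at d2 (-3.22 ± 0.15, 6.14e-10) and 58.3-fold less at d4 (-5.86 ± 0.15, 1.40e-13). Within KO cells the level fell a further 7.70-fold from d0 to d4 (-2.94 ± 0.15, 6.54e-11), against a WT change of -0.50 ± 0.15 (0.0122). The KO-WT difference was larger at d4 than at d0 (interaction -2.44 ± 0.22, adjusted p = 1.73e-06). A second Kdm1a probe set gave 9.96-, 9.96- and 30.3-fold less at d0, d2 and d4, a further 4.02-fold fall in KO cells from d0 to d4, and an interaction of -1.61. The size at d4 was thus uncertain, the more so as the KO mean of 4.76 lay close to the lower quartiles of the arrays (4.20 to 4.37). The sources used here do not give whether the probe sets lie in the deleted part of the gene.

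**Figure D2:**
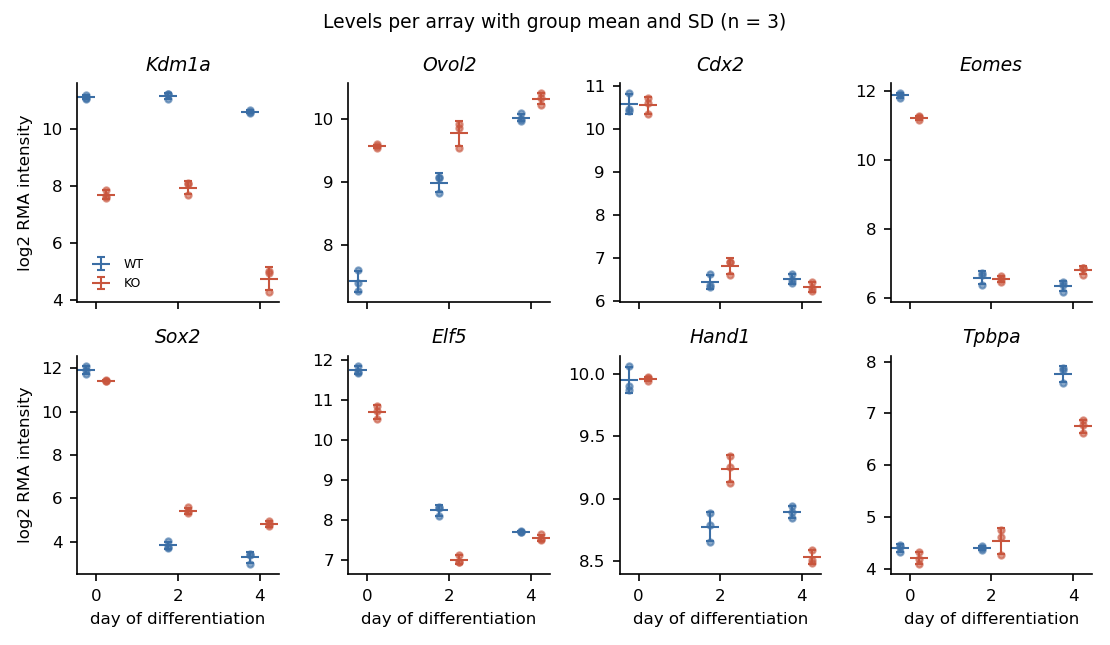
Log2 intensity of Kdm1a, Ovol2, Cdx2, Eomes, Sox2, Elf5, Hand1 and Tpbpa on the vertical axis against day and genotype; points are single arrays, bars the mean ± SD of 3. Kdm1a averaged 4.76 in KO cells at d4 and 10.62 in WT cells.

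In undifferentiated cells, the largest differences between KO and WT cells besides Kdm1a were rises in KO cells. Fhl1, which encodes a LIM-domain protein of muscle, rose most, by 13.7-fold (log2 3.77 ± 0.10 SE, n = 3 per group). It was followed by the glycolipid galactosyltransferase gene Ugt8a (3.50 ± 0.22), the glutathione transferase gene Gsta4 (3.16 ± 0.12) and the developmental transcription factor gene Sox11 (2.96 ± 0.11). Next came Pcolce2 (2.90 ± 0.16), Pwwp3b (2.77 ± 0.42), the gap junction gene Gja1 (2.65 ± 0.12) and the metal transporter gene Slc39a8 (2.50 ± 0.19). The WT means of Ugt8a (4.26) and Slc39a8 (3.39) lay near or under the arrays' lower quartiles, where the size of a change depends on background. Ovol2, a transcription factor gene of epithelial and trophoblast development, rose by 4.47-fold (2.16 ± 0.10, adjusted p = 3.92e-10). Besides Kdm1a, the largest falls were in Tmem114 (-2.22 ± 0.12), Insm1 (-2.05 ± 0.11), Il5ra (-1.70 ± 0.20), Chac1 (-1.64 ± 0.12), Nat8l (-1.52 ± 0.12), Trib3 (-1.50 ± 0.16) and D7Ertd443e (-1.45 ± 0.16). Eomes, a stem cell transcription factor gene, fell (-0.65 ± 0.10, 0.000202), while Cdx2 (-0.03 ± 0.13, 0.942), Hand1 (0.01 ± 0.08, 0.953) and Tpbpa (-0.20 ± 0.11, 0.310) did not pass.

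Genes of the stem cell state and of FGF signalling were lower in KO cells at d0. Of 15 measured trophoblast stem cell genes, 10 fell, among them Elf5 (-1.05) and Nr0b1 (-0.87), and Lrp2 rose (1.31). Adjusted over the list alone, 11 fell and 1 rose (median -0.55, camera adjusted p = 5.92e-08, adjusted p = 0.0490 with an estimated correlation). Of 14 FGF/ERK response genes, which growth factor signalling induces, 10 fell and none rose, including Egr1 (-1.45), Fosl1 (-1.16), Dusp6 (-1.12) and Spry2 (-0.92). Over the list alone 12 fell (median -0.57, 9.81e-11, adjusted p = 0.0382 with an estimated correlation). Of 14 genes of the integrated stress response, the ATF4 program, 9 fell and none rose, with Mthfd2 (-0.99) and Vldlr (-0.99) beside Chac1 and Trib3 (9 over the list alone, median -0.56, 7.13e-09). That call was lost at adjusted p = 0.226 with an estimated correlation.

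Syncytiotrophoblast and labyrinth genes rose in 5 of 11 (6 over the list alone), with Dlx3 (0.64) and Cebpa (0.40) beside Ovol2 (median 0.25, camera adjusted p = 0.000975, but adjusted p = 0.333 with an estimated correlation). Epithelial genes rose in 7 of 18 (7 alone) with no fall, led by Ocln (2.03), Cldn6 (0.72) and Ovol1 (0.72). The list median was 0.15 (camera adjusted p = 6.84e-05, adjusted p = 0.170 with an estimated correlation). Of 15 p53 targets, 5 rose (5 alone) and none fell, including Plk2 (0.50) and Cdkn1a (0.32). Their median was 0.18 (camera adjusted p = 0.00125, adjusted p = 0.170 with an estimated correlation). Cholesterol synthesis genes rose in 5 of 12 (7 alone), such as Dhcr7 (0.51) and Fdft1 (0.46). Members had a median of 0.28 (camera adjusted p = 0.000459, adjusted p = 0.170 with an estimated correlation). Mesenchymal genes rose in 5 of 19 and fell in 1 (5 and 1 alone), led by Vim (1.84), Snai2 (1.38), Fn1 (1.18) and Cdh2 (0.96). The median reached 0.05 (camera adjusted p = 0.0290, adjusted p = 0.456 with an estimated correlation). Endoderm genes rose in 4 of 12 and fell in 1 (4 and 1 alone), led by Dab2 (2.37) and Sox17 (1.33). The median of the list was 0.05 (camera adjusted p = 0.0362, adjusted p = 0.394 with an estimated correlation). Endothelial genes fell in 3 of 9 (5 alone), led by Kdr (-0.77), Pecam1 (-0.61) and Cdh5 (-0.51). Their list median was -0.27 (camera adjusted p = 0.00731, adjusted p = 0.394 with an estimated correlation).

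The members that passed at d0 also depended on the scaling. With arrays centred on their medians, syncytiotrophoblast and labyrinth genes had 2 higher (median 0.14), p53 targets 4 higher (0.07), and cholesterol synthesis genes 3 higher and 1 lower (0.18). Epithelial genes had 6 higher and 2 lower (0.05). The medians of mesenchymal (4 higher, 2 lower) and endoderm genes (3 and 1) turned to -0.05 each, and those of CoREST (-0.07), two-cell stage (-0.03) and lysosome genes (-0.07) turned as well. Centring shifted every KO-WT difference at d0 by log2 -0.10, so small positive medians had to turn and this says nothing particular of these lists. Germline genes had 2 higher and 1 lower (0.01), neuronal genes bound by REST 1 and 2 (-0.16), and DNA replication genes 6 lower (-0.15).

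The other lists did not pass at d0. None of 19 mitosis genes changed (median -0.00, camera adjusted p = 0.853), and 2 of 20 DNA replication genes fell (-0.05, 0.391). Germline genes rose in 3 of 14, among them Ddx4 (1.96, of uncertain size at a WT mean of 3.85) and Taf7l (0.75), with median 0.11 and camera adjusted p = 0.0916. The CoREST complex and its partners had 3 of 13 higher, led by Phf21a (0.65; median 0.03, camera adjusted p = 0.217), and neuronal genes bound by REST had 1 of 22 higher, Mapk8ip2 (0.52; median -0.06, camera adjusted p = 0.762). The remaining medians and camera adjusted p-values were -0.09 and 0.879 for giant cell, -0.01 and 0.535 for spongiotrophoblast and glycogen cell, 0.08 and 0.340 for two-cell stage, 0.11 and 0.283 for interferon response, and 0.13 and 0.294 for hypoxia and glycolysis genes. They were 0.03 and 0.827 for lysosome, -0.06 and 0.663 for fibroblast, -0.12 and 0.285 for pluripotent, -0.11 and 0.0963 for macrophage, and -0.06 and 0.0845 for RNA handling stress genes.

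At d0, 2284 of 18194 genes passed (1504 higher, 780 lower in KO cells), of which 225 rose and 27 fell at least 2-fold. Between 3477 and 4539 passed with all probe sets tested singly, with only the arrays compared, without the d2 arrays, with centring or with array weights. The share that was higher fell from 65.8% to 26.9% with arrays centred on their medians, but was 62.3% with quantile normalization. Centring, on the median of each array over these 18194 genes, shifts every gene of an array by the same amount. It moved the median KO-WT difference from log2 -0.03 to -0.13, so it did not balance the differences. The balance of rises and falls thus turned with that scaling but not with quantile normalization.

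At d2, KO cells kept a rise of many of the same genes and gained others. Nefl, which encodes the neurofilament light chain, rose by 8.47-fold (log2 3.08 ± 0.11 SE, n = 3 per group). It was followed by the protease inhibitor gene Ctla2a (2.68 ± 0.13), Ugt8a (2.65 ± 0.22) and the complement protease gene C1s1 (2.60 ± 0.09). The endocytic receptor gene Lrp2 (2.56 ± 0.18), Fhl1 (2.55 ± 0.10), Gja1 (2.48 ± 0.12) and Selenop (2.41 ± 0.08) came next. Ugt8a averaged only 3.74 in WT cells, so the size of its rise was uncertain. Falls were smaller, and besides Kdm1a were largest in the trophoblast transcription factor gene Elf5 (-1.24 ± 0.09), the chemerin receptor gene Cmklr1 (-1.19 ± 0.12) and Syne3 (-1.17 ± 0.12). Slco4a1 (-1.14 ± 0.11), Itga7 (-1.11 ± 0.12), C1ql2 (-1.10 ± 0.17) and Rassf5 (-1.06 ± 0.11) followed. Ovol2 rose (0.79 ± 0.10, adjusted p = 4.86e-05), and so did Hand1 (0.46 ± 0.08, 0.000439), whose call was lost with only the d2 arrays in the fit (0.0586). Cdx2 (0.36 ± 0.13, 0.0753), Eomes (-0.05 ± 0.10, 0.808) and Tpbpa (0.14 ± 0.11, 0.461) did not pass. Cdx2 did pass without the 2 d2 arrays that stood apart (0.55, 0.0111) and with array weights (0.54, 0.00132).

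Mesenchymal genes were higher in KO cells at d2 in 8 of 19 (9 over the list alone), with Cdh2 (1.84), Vim (1.66), Snai2 (0.95) and Fn1 (0.77). As a list their median was 0.18 (camera adjusted p = 0.000129, adjusted p = 0.226 with an estimated correlation). Epithelial genes rose in 5 of 18 and fell in 2 (8 and 2 alone), led by Ocln (1.28) and Ovol1 (0.96). The list median was 0.15 (camera adjusted p = 0.00572, adjusted p = 0.340 with an estimated correlation). DNA replication genes fell in 8 of 20 (10 alone), by small amounts such as Cdc45 (-0.38) and Mcm4 (-0.37). Their median was -0.19 (camera adjusted p = 0.000276, adjusted p = 0.294 with an estimated correlation). Of 15 p53 targets, 4 rose (4 alone), such as Plk2 (0.61) and Mdm2 (0.24). Members had a median of 0.14 (camera adjusted p = 0.0187, adjusted p = 0.333 with an estimated correlation). Syncytiotrophoblast and labyrinth genes fell in 5 of 11 and rose in 2 (7 and 2 alone), with Tfeb (-0.60) and Dlx3 (-0.55) lower and Esx1 (0.48) higher (median -0.25, p = 0.0349, adjusted p = 0.513 with an estimated correlation). That call was also lost without the 2 arrays that stood apart (camera adjusted p = 0.0748).

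Stem cell genes split at d2 into 3 higher, with Lrp2 and Sox2, and 3 lower of 15, with Satb1 (-0.77) beside Elf5; their median was -0.05, their mean 0.18 and the camera adjusted p = 0.732. FGF/ERK response genes had 3 higher and 1 lower of 14, with Etv5 (0.79) and Dusp6 (0.45) higher and Myc (-0.62) lower (median 0.07, camera adjusted p = 0.298). Sizes were uncertain for Sox2, Etv5 and Dusp6, whose WT means at d2 (3.83, 4.19 and 4.24) lay near or under the arrays' lower quartiles, and so was the mean of the stem cell list. Integrated stress response genes had 5 lower and 1 higher of 14 (-0.13, 0.104), and interferon response genes 3 higher and 1 lower of 13 (0.13, 0.0845).

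With arrays centred on their medians at d2, mesenchymal genes had 6 higher and 3 lower (median 0.04), epithelial genes 4 and 4 (0.01), and p53 targets 1 and 1 (0.01). Centring shifted every KO-WT difference at d2 by log2 -0.14, so all list medians moved by that amount. A rise of these lists in level thus depended on the scaling, while the distance of their medians from other genes did not. Falls grew to 15 of the DNA replication (-0.33) and 9 of the syncytiotrophoblast and labyrinth genes (-0.38), with 2 of the latter higher. The small positive medians of FGF/ERK response (3 higher, 4 lower, -0.06) and interferon response genes (3 and 3, -0.00) turned, which follows from that shift alone. Stem cell genes had 3 higher and 5 lower (-0.18), and integrated stress response genes 1 and 7 (-0.27).

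At d2, 2653 genes passed (1690 higher, 963 lower), 210 with a rise and 9 with a fall of at least 2-fold. Without the 2 arrays that stood apart, a choice made after seeing the data, 3146 passed. Only 724 passed with the d2 arrays fitted alone, where the spread was that of d2 and rested on fewer arrays, but 5474 with array weights. With centring 6832 passed, 17.4% of them higher against 63.7% before and 59.8% with quantile normalization.

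At d4, more genes passed between KO and WT cells than on either earlier day. Nefl was 20.5-fold higher (log2 4.35 ± 0.11 SE, n = 3 per group). Next were Ugt8a (3.81 ± 0.22), Bex4 (3.02 ± 0.08), the neuronal ubiquitin hydrolase gene Uchl1 (2.91 ± 0.16) and the N-cadherin gene Cdh2 (2.80 ± 0.16). Fhl1 (2.77 ± 0.10), the imprinted gene Mest (2.73 ± 0.09) and the kinase inhibitor gene Pkib (2.69 ± 0.18) followed. Ugt8a (3.07) and Pkib (3.89) had low WT means, so the sizes of their rises were uncertain. After Kdm1a, the largest falls were in the interferon-induced GTPase gene Gbp6 (-2.37 ± 0.14), the mitochondrial folate enzyme gene Mthfd2 (-2.36 ± 0.16) and the glucose transporter gene Slc2a2 (-2.29 ± 0.14). Trib3 (-2.23 ± 0.16), Pinlyp (-2.21 ± 0.15), the interferon-induced GTPase gene Ifi47 (-2.15 ± 0.11) and the endoplasmic reticulum stress gene Herpud1 (-2.10 ± 0.14) were lower as well. Tpbpa, a spongiotrophoblast marker, was 2.02-fold lower (-1.01 ± 0.11, adjusted p = 3.11e-06). Hand1 was lower (-0.36 ± 0.08, 0.00190) and Eomes higher (0.47 ± 0.10, 0.00176), while Cdx2 did not pass (-0.19 ± 0.13, 0.312). Ovol2 was higher by 0.30 ± 0.10 (0.0388), a call lost with centred arrays (0.18, 0.129), with the replicate block (0.0539) and in 5 of 6 fits with an array left out.

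Giant cell genes were lower in KO cells at d4 in 8 of 12 (8 over the list alone) with none higher, among them the placental hormone genes Prl4a1 (-1.62), Prl2a1 (-1.56) and Prl7d1 (-1.10) and the placental cathepsin gene Ctsj (-0.92). The median reached -0.56 (camera adjusted p = 0.000275, adjusted p = 0.0784 with an estimated correlation). Interferon response genes fell in 11 of 13, with none higher over all genes and 11 lower and 1 higher over the list alone, including Irf7 (-1.44), Oas1a (-1.39), Oasl2 (-1.17) and Ifit3 (-1.17). The median of the list was -1.04 (camera adjusted p = 3.19e-08, adjusted p = 0.0558 with an estimated correlation). Integrated stress response genes fell in 11 of 14 (13 alone) with none higher, with Atf4 (-1.32) and Ddit4 (-1.30) beside Mthfd2 and Trib3 (median -0.97, p = 4.38e-10, adjusted p = 0.170 with an estimated correlation). Of 15 p53 targets, 8 rose and 1 fell (8 and 2 alone), led by Plk2 (1.37) and Zmat3 (1.03). Their list median was 0.46 (camera adjusted p = 0.000367, adjusted p = 0.147 with an estimated correlation). Epithelial genes rose in 10 of 18 and fell in 4 (10 and 4 alone), with Cldn6 (1.54), Ocln (1.20), Epcam (1.17) and Cldn3 (1.08) higher. As a list their median was 0.29 (camera adjusted p = 0.00189, adjusted p = 0.294 with an estimated correlation). Mesenchymal genes rose in 7 of 19 and fell in 1 (7 and 3 alone), with Vim (1.81) and Zeb1 (1.63) beside Cdh2. The list median was 0.17 (camera adjusted p = 0.0109, adjusted p = 0.394 with an estimated correlation). DNA replication genes fell in 9 of 20 and rose in 1 (10 and 1 alone), with Mcm3 (-0.73) and Mcm4 (-0.46) lower and Ccne1 (0.63) higher. Their median was -0.20 (camera adjusted p = 0.0230, adjusted p = 0.485 with an estimated correlation).

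With arrays centred on their medians at d4, giant cell (9 lower, median -0.69), interferon response (11 lower, -1.17) and integrated stress response genes (14 lower, -1.09) fell as before. Centring shifted every KO-WT difference at d4 by log2 -0.13, so it deepened falls and could not test them. Mesenchymal genes then had 5 higher and 6 lower (0.04), epithelial genes 9 and 5 (0.16), p53 targets 8 and 3 (0.33), and DNA replication genes 1 and 15 (-0.33). Among lists that did not pass, stem cell genes had 5 higher and 5 lower (0.03), and in the lists that follow falls outnumbered rises. The counts were 4 higher and 8 lower for neuronal genes bound by REST (-0.21), 1 and 5 for germline (-0.13), and 2 and 8 for spongiotrophoblast and glycogen cell genes (-0.23). They were 1 and 11 for lysosome (-0.25), 4 and 9 for hypoxia and glycolysis (-0.31), 0 and 7 for syncytiotrophoblast and labyrinth (-0.34), 2 and 6 for fibroblast (-0.18), and 0 and 3 for macrophage genes (-0.19). Of the lower germline genes, Sycp3, Tex11, Dpep3 and Slc25a31 averaged under 4.37, the highest lower quartile of an array, in all 6 groups. So did Snap25, Nefm and Unc13a of the neuronal list, and Prl8a8 and Prl3c1 of the spongiotrophoblast list. Falls in these lists thus partly rest on low values.

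Spongiotrophoblast and glycogen cell genes split at d4 into 5 lower, with Prl6a1 (-1.86) and Psg18 (-1.24, of uncertain size at a KO mean of 4.06) beside Tpbpa, and 3 higher of 17, with Flt1 (1.10; median -0.10, camera adjusted p = 0.537). Stem cell genes were higher in 7 of 15 and lower in 3, with Lrp2 (1.39), Bmp4 (0.68) and Sox2 higher, the last by an uncertain amount over a low WT mean of 3.28 (median 0.15, camera adjusted p = 0.119). Neuronal genes bound by REST had 4 of 22 higher besides 1 lower, with Mapk8ip2 (1.86), Vgf (0.98) and Tubb3 (0.62) beside Nefl; their median was -0.09, their mean 0.28 and the camera adjusted p = 0.284. Germline genes had Taf7l (2.18) and Ddx4 (0.56) higher of 14 (median -0.00, mean 0.17, camera adjusted p = 0.639), but Ddx4 did not pass with centring (0.43, adjusted p = 0.0837) and was low in both genotypes (means 3.13 and 3.69). Hypoxia and glycolysis genes split into 4 higher and 8 lower of 15 (-0.18, 0.708), and lysosome genes into 1 and 6 of 15 (-0.13, 0.320). The split was 1 and 6 of 11 for syncytiotrophoblast and labyrinth genes (-0.21, 0.102), 2 and 2 of 14 for fibroblast genes (-0.06, 0.813), and 0 and 1 of 10 for macrophage genes (-0.06, 0.590).

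At d4, 4783 genes passed (2308 higher, 2475 lower), 445 with a rise and 124 with a fall of at least 2-fold. Array weights gave 7356, probe sets tested singly 8367, and centring 8799 with 20.2% higher against 48.3% before. With quantile normalization 46.2% were higher.

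**Figure D3:**
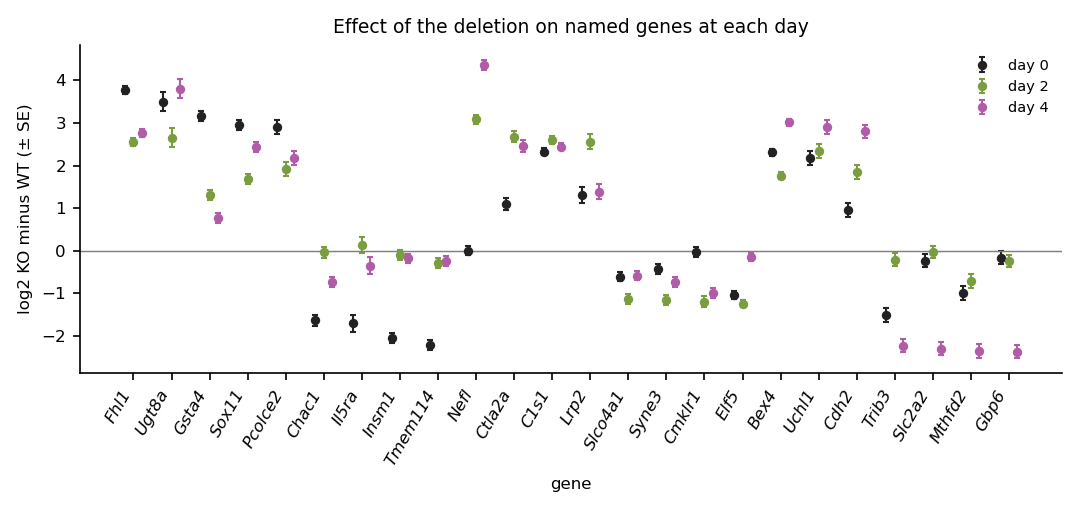
KO minus WT difference at d0, d2 and d4 on the vertical axis (log2, points with SE, n = 3 arrays per group) for 24 named genes on the horizontal axis. Nefl was higher in KO cells at d2 and d4 (3.08 and 4.35), and Fhl1 on all 3 days (3.77, 2.55 and 2.77).

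Many of the same genes differed between KO and WT cells on all 3 days. Of the genes that passed, 688 were higher and 141 lower in KO cells at all 3 stages, 829 together. Between d0 and d2, 891 genes were higher at both (139.7 expected from independent calls) and 188 lower at both (41.3 expected), with 72 in opposite directions (152.1 expected). Between d0 and d4 the counts were 907 (190.8), 321 (106.1) and 176 opposite (303.5), and between d2 and d4 they were 1134 (214.4), 518 (131.0) and 117 opposite (352.1). The comparisons shared no array, but all cells came from 1 line. They also shared 1 spread per gene in the fit, so a gene with a small spread passed more easily on every day. The numbers expected from independent calls were thus likely too low. The 829 became 486 with only the arrays compared, where each day had its own spread, 1500 with array weights and 1795 with centring.

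In control cells, genes of the stem cell state fell within 2 days. At d2 the pluripotency factor gene Sox2 was lower by log2 -8.08 ± 0.13 (SE, n = 3 per group). The FGF pathway genes Spry2 (-6.00 ± 0.11), Etv5 (-5.69 ± 0.12) and Dusp6 (-5.60 ± 0.12) fell with it. All 4 ended near or under the arrays' lower quartiles (4.20 to 4.37), with WT means at d2 of 3.83, 3.67, 4.19 and 4.24. Signal over background was not analysed here, so the sizes and order of these falls were uncertain. Eomes (-5.29 ± 0.10), Cdx2 (-4.12 ± 0.13) and Hand1 (-1.17 ± 0.08) fell too. Cmklr1 (4.22 ± 0.12), the matricellular gene Ccn2 (3.58 ± 0.09), Ldoc1 (3.42 ± 0.12) and Igfbp2 (3.36 ± 0.11) rose most. Ovol2 rose (1.57 ± 0.10), and Tpbpa (0.00 ± 0.11, adjusted p = 0.993) did not pass. By d4 the placental genes Prl2b1 (5.99 ± 0.18) and Prl7d1 (5.77 ± 0.32), the plasminogen activator gene Plat (6.18 ± 0.14, 72.7-fold), Postn (5.64 ± 0.29), Plac8 (5.63 ± 0.09) and Lonrf3 (5.32 ± 0.10) had risen most, with Tpbpa (3.37 ± 0.11) and Ovol2 (2.61 ± 0.10). Tpbpa started near the arrays' lower quartiles at d0 (4.40), so the size of its rise was uncertain. Falls at d4 were large in Sox2 (-8.64 ± 0.13, to a mean of 3.28, so of uncertain size), Pou3f1 (-6.64 ± 0.12), Sorl1 (-5.92 ± 0.12), Zic5 (-5.69 ± 0.13), Eomes (-5.54 ± 0.10) and Bmp4 (-5.44 ± 0.12), with Cdx2 (-4.06 ± 0.13) and Hand1 (-1.05 ± 0.08).

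In WT cells at d2, stem cell genes fell in 10 of 15 and rose in 2 (10 and 3 over the list alone; median -2.30, camera adjusted p = 5.97e-10, adjusted p = 0.0382 with an estimated correlation). FGF/ERK response genes fell in 13 of 14 and rose in 1 (13 and 1 alone; -2.87, 9.89e-15, adjusted p = 0.0239 with an estimated correlation). The estimated correlation ended 5 other calls. They were the integrated stress response (11 of 14 lower, 11 alone, with Chac1 at -2.24; -0.93, 3.71e-06, adjusted p = 0.333 with an estimated correlation) and cholesterol synthesis (9 of 12 lower, 10 alone, with Idi1 at -1.26; -0.50, 9.63e-05, adjusted p = 0.139 with an estimated correlation). Syncytiotrophoblast and labyrinth genes followed (8 of 11 higher, 8 alone, with Dlx3 at 2.66 and Cebpa at 2.17; 1.40, 0.00199, adjusted p = 0.354 with an estimated correlation). The last were pluripotent (7 of 12 lower, 7 alone, with Dppa4 at -1.96; -0.51, 0.00426, adjusted p = 0.170 with an estimated correlation) and interferon response genes (8 of 13 lower, 8 alone, with Ifih1 at -1.48; -0.30, 0.00565, adjusted p = 0.333 with an estimated correlation).

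By d4 in WT cells all 19 mitosis genes were lower, with Mki67 at -2.98 and Cenpf at -2.60 (19 over the list alone; median -1.97, camera adjusted p = 1.95e-11, adjusted p = 0.0239 with an estimated correlation). FGF/ERK response genes were lower in 12 of 14 (12 alone; -2.67, 3.31e-09, adjusted p = 0.0490 with an estimated correlation). Stem cell genes were lower in 11 of 15 (11 alone; -2.21, 2.45e-07, adjusted p = 0.0558 with an estimated correlation). Interferon response genes rose in 12 of 13, led by Rsad2 (2.79) and by Ifit2 (2.51, from a low d0 mean of 4.25; 12 alone; 1.79, 1.44e-07, adjusted p = 0.0645 with an estimated correlation). Giant cell genes rose in 8 of 12 (8 alone), with Prl4a1 (4.47) and Ctsq (3.66), while Hand1 of that list fell (-1.05). The list median was 1.29 (camera adjusted p = 0.00225, adjusted p = 0.150 with an estimated correlation). Syncytiotrophoblast and labyrinth genes rose in 8 of 11, with Gjb2 (4.46), Dlx3 (3.16) and Pparg (2.52; 8 alone; 1.85, 0.000131, adjusted p = 0.274 with an estimated correlation). Lysosome genes rose in 10 of 15 with none lower, such as Ctsa (1.39; 13 alone; 0.48, 0.000304, adjusted p = 0.394 with an estimated correlation). DNA replication genes fell in 18 of 20, with Gins1 at -1.91 (18 alone; -0.98, 3.21e-09, adjusted p = 0.0784 with an estimated correlation). Cholesterol synthesis genes fell in 10 of 12, with Mvd at -2.46 (10 alone; -1.08, 0.000975, adjusted p = 0.199 with an estimated correlation). Of the p53 targets, 10 of 15 fell, with Zmat3 at -2.17 (10 alone; -0.69, 0.00719, adjusted p = 0.277 with an estimated correlation). Pluripotent genes fell in 6 of 12, with Dppa4 at -3.27 (6 alone; -0.38, 0.0488, adjusted p = 0.333 with an estimated correlation). That last call was also lost with the replicate block (0.0534). Spongiotrophoblast and glycogen cell genes rose in 8 of 17 and fell in 3, led by Prl6a1 (4.48, of uncertain size from a d0 mean of 3.72) and Tpbpa, but did not pass as a list (median 0.20, camera adjusted p = 0.104).

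From d0 to d2, 8617 genes passed in WT cells (5366 higher, 3251 lower), 553 with a rise and 834 with a fall of at least 2-fold. From d0 to d4, 8615 passed (4303 higher, 4312 lower), 1187 with a rise and 1321 with a fall of at least 2-fold. Probe sets tested singly gave 17628 and 17924, and without WT replicate 3 and KO replicate 2 of d2, 10540 passed at d2. With centring the higher share at d4 rose from 49.9% to 64.7%.

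KO cells went through much of the same course. At d4 Plat (5.71 ± 0.14), Prl2b1 (5.25 ± 0.18), Slco4a1 (5.18 ± 0.11) and Postn (5.01 ± 0.29) rose most (log2 ± SE, n = 3 per group). Sox2 (-6.59 ± 0.13), Pou3f1 (-5.15 ± 0.12), Sorl1 (-4.95 ± 0.12) and Ddah1 (-4.65 ± 0.12) fell most. Tpbpa (2.55 ± 0.11, of uncertain size because of its low KO mean of 4.20 at d0) and Ovol2 (0.76 ± 0.10) rose, and Cdx2 (-4.22 ± 0.13), Eomes (-4.43 ± 0.10) and Hand1 (-1.43 ± 0.08) fell. At d2 Cdx2 (-3.74 ± 0.13), Eomes (-4.69 ± 0.10) and Hand1 (-0.72 ± 0.08) were already lower, and Tpbpa was slightly higher (0.34 ± 0.11, adjusted p = 0.0240, lost at 0.0754 with only the arrays compared and in 4 of 6 fits with an array left out). Ovol2 did not pass at d2 (0.20 ± 0.10, 0.124), but passed without the 2 arrays that stood apart (0.32, 0.00494) and with array weights (0.28, 0.00238). Kdm1a did not pass between d0 and d2 in KO cells (0.25 ± 0.15, 0.201), but did with array weights (0.35, 0.0385) and with the mean over its probe sets (0.26, 0.0425).

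In KO cells at d2, stem cell genes fell in 10 of 15 (10 over the list alone; median -2.12, camera adjusted p = 9.00e-10, adjusted p = 0.0382 with an estimated correlation). FGF/ERK response genes fell in 10 of 14 (11 alone; -1.96, 8.90e-13, adjusted p = 0.0307 with an estimated correlation). Cholesterol synthesis genes fell in 11 of 12, with Idi1 at -1.54 (11 alone; -0.78, 6.39e-09, adjusted p = 0.0382 with an estimated correlation). The estimated correlation ended the other calls at d2. These were the integrated stress response (7 of 14 lower; -0.28, 0.00195, adjusted p = 0.500 with an estimated correlation) and interferon response (9 of 13 lower; -0.43, 0.00230, adjusted p = 0.295 with an estimated correlation). Pluripotent (5 of 12 lower; -0.13, 0.0163, adjusted p = 0.258 with an estimated correlation) and DNA replication genes (8 of 20 lower, 5 higher; -0.12, 0.0318, adjusted p = 0.513 with an estimated correlation) followed. Endothelial (3 of 9 lower, 2 higher; -0.18, 0.0469, adjusted p = 0.513 with an estimated correlation) and RNA handling stress genes (9 of 14 higher, with Hspa1b at 1.05; 0.60, 0.0469, adjusted p = 0.608 with an estimated correlation) were the last. Without the 2 arrays that stood apart, 4 of these calls were lost: pluripotent (0.0782), DNA replication (0.143), endothelial (0.142) and RNA handling stress (0.0748). The endothelial call was also lost with quantile normalization (0.0550) and with the replicate block (0.0509).

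In KO cells at d4, all 19 mitosis genes fell (19 over the list alone; median -1.65, camera adjusted p = 2.63e-11, adjusted p = 0.0239 with an estimated correlation), as did 12 of 14 FGF/ERK response genes (12 alone; -1.63, 5.71e-09, adjusted p = 0.0490 with an estimated correlation). The other calls did not hold with an estimated correlation. Among them were DNA replication (19 of 20 lower; -1.09, 1.38e-10, adjusted p = 0.0558 with an estimated correlation) and stem cell genes (10 of 15 lower; -1.79, 3.16e-05, adjusted p = 0.129 with an estimated correlation). Further ones were cholesterol synthesis (10 of 12 lower; -1.20, 7.89e-06, adjusted p = 0.0784 with an estimated correlation) and integrated stress response genes (10 of 14 lower, 3 higher; -0.99, 0.0155, adjusted p = 0.578 with an estimated correlation). The p53 targets (9 of 15 lower, 1 higher; -0.36, 0.0175, adjusted p = 0.331 with an estimated correlation) lost theirs too. Of lists that rose, the calls lost were syncytiotrophoblast and labyrinth (8 of 11 higher, 2 lower; 1.02, 0.00162, adjusted p = 0.341 with an estimated correlation) and lysosome (11 of 15 higher, 1 lower; 0.51, 0.00176, adjusted p = 0.444 with an estimated correlation), and likewise interferon response (9 of 13 higher, 1 lower; 0.34, 0.00189, adjusted p = 0.294 with an estimated correlation) and giant cell genes (7 of 12 higher, 2 lower; 0.58, 0.0469, adjusted p = 0.333 with an estimated correlation).

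From d0 to d2, 7489 genes passed in KO cells (4819 higher, 2670 lower), 345 with a rise and 563 with a fall of at least 2-fold. From d0 to d4, 8056 passed (3798 higher, 4258 lower), 907 with a rise and 1023 with a fall of at least 2-fold. Array weights gave 11523 at d2, probe sets tested singly gave 15289 and 16567, and 9599 passed at d2 without the 2 arrays that stood apart. With centring the higher share at d4 rose from 47.1% to 59.3%.

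**Figure D4:**
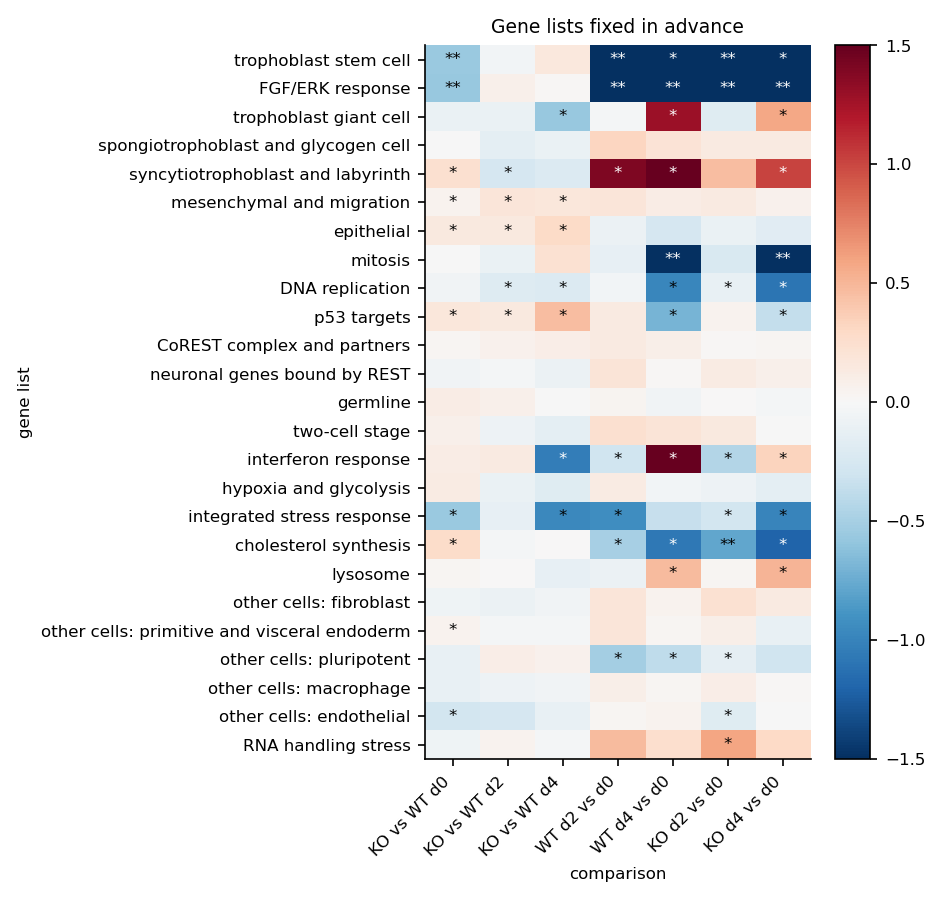
Median log2 change of the measured members of each of 25 gene lists (vertical axis) in 7 comparisons (horizontal axis), with colour from -1.5 to 1.5; 1 star marks a camera call, 2 stars a call that also held with an estimated correlation. Mitosis genes fell in both genotypes at d4 (medians -1.97 and -1.65).

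The response to differentiation differed between the genotypes at 656 genes by d2 (369 with a more positive and 287 with a more negative KO-WT difference than at d0) and at 1883 genes by d4 (880 and 1003). Nefl moved most, with interactions of 3.08 ± 0.16 SE and 4.35 ± 0.16: it fell in WT cells by d4 (-2.27) and rose in KO cells (2.08). Sox2 fell less in KO cells by d2 (interaction 2.10 ± 0.19, of uncertain size because of the low WT level of 3.83), and Eomes less by d4 (1.12 ± 0.14, adjusted p = 4.75e-05). Ovol2 rose less (-1.37 ± 0.15 by d2, -1.85 ± 0.15 by d4, 5.88e-07), from the higher KO level at d0, and so did Tpbpa by d4 (-0.82 ± 0.16, 0.00233). The size for Tpbpa was uncertain, since its d0 means of 4.40 in WT and 4.20 in KO cells lay near the arrays' lower quartiles. Among lists that held with an estimated correlation, FGF/ERK response (median 0.73 by d2, 0.70 by d4) and stem cell genes (0.40, 0.43) fell less in KO cells, from their lower level at d0. Interferon response (-1.03) and giant cell genes (-0.67) rose less by d4. The 656 became 1055 without the 2 d2 arrays that stood apart, 2327 with array weights and 375 with only the arrays compared. The 1883 became 3326 without the d2 arrays, 3970 with array weights and 2960 with probe sets tested singly.

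Of 1881 genes that passed in the d4 interaction and in the d4 minus d0 change of either genotype, 1429 (76.0%) had the smaller absolute change in KO cells and 452 (24.0%) the larger. Genotypes alike would give 50%, and this selection was chosen after seeing the data. Among the 1655 of them that passed in WT cells, signs were opposite for 247, and 79 passed in the opposite direction in KO cells. Across all genes the SD of the d4 minus d0 change was 0.798 in WT and 0.663 in KO cells, and the changes correlated between genotypes (r = 0.909, no shared array).

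Across all genes, the KO-WT difference at d0 correlated weakly with the WT change from d0 to d4 (r = 0.137, jackknife SE 0.0250 over arrays, Spearman 0.0807). The WT d0 arrays enter both sides, so unchanged groups were simulated with the same sharing. Their covariance was 0.00472 against 0.0311 measured, an excess of 0.0264. Their correlation was 0.498 on average and at most 0.519 in 100 draws. The draws held noise only, so that correlation follows from the sharing itself. It is not comparable with 0.137, whose WT side also held the changes of differentiation. Part of the excess may come from the shared controls, since 3 arrays cannot be divided into parts of at least 2 each. Against the WT change from d2 to d4, which shares no array, the correlation was -0.0194 (Spearman -0.0472). That change covers only the later part of the course, after Sox2, Eomes and Cdx2 had already fallen. It therefore cannot show whether the 0.137 comes from the shared arrays. The KO-WT difference at d2 correlated at -0.179 with the WT change from d0 to d4, and that at d4 at -0.153 with the WT change from d0 to d2, neither sharing an array.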

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

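The interaction tests below were fixed before the data were seen, while every explanation test was chosen after the result was seen, except the regroupings of labels and the test for compressed signal. The results are listed because the KO-WT difference on d2 or d4 differed from that at d0 by the interaction test (limma, adjusted p under 0.05).

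At d2 the difference had changed at 656 genes. Of 100 labellings of genotype within each day, the real one included, 3 gave as many or more, the highest 1624. The most positive interactions (log2) were Nefl 3.08, Sox2 2.10, Insm1 1.95 and Tmem114 1.93, and the most negative were Fgfbp1 -2.15, Gsta4 -1.84, Vav3 -1.74 and Itih5 -1.44. The sizes for Sox2 and Insm1 were uncertain, as their WT means at d2 (3.83 and 4.26) were low. Eomes (0.60), Hand1 (0.45) and Ovol2 (-1.37) also passed, but the calls of Eomes and Hand1 were fragile. Quantile normalization ended both (0.0562 and 0.0720), the replicate block (0.0537) and only the arrays compared (0.0984) ended that of Hand1, and leaving out 1 array ended them in 4 and 7 of 12 fits. Medians of the lists that passed were 0.40 for trophoblast stem cell and 0.73 for FGF/ERK response genes, which also held with an estimated correlation (adjusted p = 0.0382 and 0.0239). The others did not hold: syncytiotrophoblast and labyrinth (-0.38, 0.0645), DNA replication (-0.12, 0.394), integrated stress response (0.38, 0.303), cholesterol synthesis (-0.24, 0.294), pluripotent (0.31, 0.170) and RNA handling stress genes (0.14, 0.553).

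At d4 the difference had changed at 1883 genes, and 4 of 100 labellings, the real one included, gave as many or more, the highest 2451. The high counts at d4 came from relabellings that kept the genotypes apart on 1 of the days, which turns the contrast into the effect of genotype on that day. The most positive interactions were Nefl 4.35, Mest 2.68, Ninl 2.43 and Nnt 2.33, and the most negative Pinlyp -2.94, AA467197 -2.69, Dab2 -2.63 and Fthl17a -2.61. The size for Ninl was uncertain, as its WT mean at d4 (3.77) was low. Eomes (1.12), Hand1 (-0.37), Kdm1a (-2.44), Ovol2 (-1.85) and Tpbpa (-0.82) also passed, but the call of Hand1 was lost with quantile normalization (0.0616), with the replicate block (0.0597) and in 9 of 12 fits with an array left out. The size for Tpbpa was uncertain because of its low d0 means (4.40 in WT and 4.20 in KO cells). List medians that held with an estimated correlation were 0.43 for trophoblast stem cell (adjusted p = 0.0387), 0.70 for FGF/ERK response (0.0451), -0.67 for giant cell (0.0490) and -1.03 for interferon response genes (0.0307). The calls for syncytiotrophoblast and labyrinth (-0.39, 0.149), p53 target (0.34, 0.394), two-cell stage (-0.24, 0.170), integrated stress response (-0.41, 0.513), cholesterol synthesis (-0.26, 0.397) and pluripotent genes (0.26, 0.274) were lost.

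For comparisons of 2 groups the 6 arrays allow 10 splits, and 10 splits cannot give a share under 0.05. In each of the 7 comparisons the real split gave the highest count, a share of 1 of 10. The highest other count was 0 for KO against WT at d0 and at d4 and for all 4 changes over time. At d2 it was 2595 against 2653, from the split that put WT replicate 3, KO replicate 2 and KO replicate 3 together.

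The first pattern weighed, with tests chosen after the result was seen, was that WT replicate 3 and KO replicate 2 stood apart at d2. A swapped genotype label was ruled out, since WT replicate 3 held more Kdm1a RNA than KO replicate 2 by log2 3.38. Collection at an earlier point of the course could not be told. Both arrays also deviated toward d4 (smaller coefficient of the d4 minus d2 change 0.176). But the d0 and d4 terms of that test shared the same d2 arrays, and it assumed a straight course between days. Arrays of d0 or d4 under a d2 label were ruled out, since on a line from d0 (0) to d4 (1) of their genotype both arrays lay at least 0.454 from either end, and no d0 or d4 array lay over 0.0303 from its own. A difference in culture or processing shared by these 2 arrays remains possible.

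The second pattern was the smaller response of KO cells to 4 days of differentiation. Compressed signal on the KO arrays of d4 should have shrunk nearly every change. Yet 11.4% of the genes that passed in both tests changed more in KO cells (exact 95% interval 9.87 to 13.0), so it was unlikely as the only cause. The interval treats genes as independent and does not measure the spread between arrays. Noise in the shared WT arrays and selection on the WT change lower the share of 11.4%. With genes that passed in either genotype 24.0% changed more in KO cells. A more complete deletion at d4 could not be told apart. Of the genes that passed at both d0 and d4, 12.5% had opposite directions, which effects that only grow would not give. But the test assumed that the deletion acts in the same direction in stem cells and differentiated cells. Opposite directions were also fewer than expected from independent calls (176 against 303.5), and Kdm1a RNA did fall further in KO cells by d4. Slower progress along the WT course could not be told: the KO-WT difference at d4 correlated at -0.153 across genes with the WT change from d0 to d2. A later or weaker differentiation of part of the cells is therefore possible and would need single cells or later days.

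The third pattern, weighed with tests chosen after the result was seen, was the lower level of FGF/ERK response genes in KO cells at d0 (median -0.57). Handling before lysis could not be told apart. The RNA handling stress genes outside that list had a median of -0.0436 ± 0.0527 but went both ways, with Dusp1 lower (-0.60, adjusted p = 7.02e-06) and Hspa1a slightly higher (0.16, not passing). Exposure to 4-hydroxytamoxifen itself could not be told from the deletion, since 0 control arrays are stated as exposed. Reduced FGF signalling upon loss of Lsd1 is 1 possible reading. Control cells treated with the drug would separate drug from deletion, while signalling itself was not measured here.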

How the results depend on the processing

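Kdm1a kept its direction and call on all 3 days under every alternative (log2 -3.53 to -3.36, -3.36 to -3.08 and -6.00 to -5.39 with 1 value per gene). The second probe set tested singly gave -3.32, -3.32 and -4.92, so the size at d4 was less certain. Of 2256 values of named genes under alternatives, 2206 kept their side of the threshold, 39 lost the call, 11 gained it and 0 turned direction. An estimated correlation ended 61 of 78 list calls, fry ended 1 and added 60, quantile normalization ended 1 and added 6, and the replicate block ended 2; the block changed no count of genes by over 1.5 times. Replicate numbers did not pair between KO and WT arrays of a day. Deviations from the group mean of arrays with the same number correlated across genes at 0.27, -0.80 and -0.65 at d2. The 2 arrays that stood apart weigh on these d2 values. The values were -0.08, -0.05 and 0.02 at d0, and -0.17, -0.17 and 0.08 at d4. Counts follow in the order KO against WT at d0, d2 and d4, WT d2 and d4, KO d2 and d4, and the interactions at d2 and d4. A 2-fold minimum left 252, 219, 569, 1387, 2508, 908, 1930, 97 and 338, since it adds a condition. Probe sets tested singly gave 3477 at d0, 8367 at d4, 17628, 17924, 15289 and 16567 over time, and 2960 for the d4 interaction, since more units are tested. For the rest the cause was not tested. Array weights gave 4539, 5474 and 7356 for KO against WT, 11523 for KO d2, and 2327 and 3970 for the interactions. Only the arrays compared gave 3581 at d0, 724 at d2, and 375 and 3326 for the interactions. That setting leaves out the spread of the other days, and replicates varied most at d2. Arrays centred on their medians over the 18194 genes gave 4252, 6832 and 8799 for KO against WT and shifted the median gene by log2 -0.10, -0.14 and -0.13. That moved it from -0.03, -0.03 and -0.06 to -0.13, -0.17 and -0.19, farther from no difference. The higher share then went from 65.8 to 26.9%, from 63.7 to 17.4% and from 48.3 to 20.2%, from 49.9 to 64.7% for WT d4, from 47.1 to 59.3% for KO d4 and from 56.3 to 44.2% for the d2 interaction. Quantile normalization gave higher shares of 62.3, 59.8 and 46.2% for KO against WT. Settings chosen after seeing the data gave 3616 at d0 and 3326 for the d4 interaction without the d2 arrays, and 1055 for the d2 interaction without the 2 that stood apart. Leaving out each array in turn gave 1630 to 1787, 2020 to 3819, 3666 to 4479, 6860 to 9814, 7887 to 8175, 5739 to 8680, 7313 to 7571, 440 to 873 and 1478 to 1732. The 829 genes changed on all 3 days became 1795 with centring, 1500 with array weights, 486 with only the arrays compared, and 666 to 925 with an array left out. The correlation of 0.137 between the KO-WT difference at d0 and the WT course was 0.169 over genes above the median level and 0.124 to 0.152 with an array left out. Against the d4 minus d2 change, which shares no array, it was -0.0194, but that is a different part of the course. Signal over background was not analysed here, so the lowest detectable level was not judged.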

Other observations

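The genes named here, and the hypothesis tested, were chosen after their values were seen. Among neuronal genes bound by REST, Nefl, Mapk8ip2 (1.86), Vgf (0.98) and Tubb3 (0.62) were higher in KO cells at d4 and 1 of 22 was lower (list median -0.09). Centring arrays on their medians shifted every KO-WT difference at d4 by log2 -0.13. With it 4 were higher and 8 lower, so the balance depended on the scaling. Of the germline genes, Ddx4 and Taf7l were higher on all 3 days, Taf7l by log2 0.75, 1.78 and 2.18 and Ddx4 by 1.96, 0.73 and 0.56, but at d4 Ddx4 did not pass with centred arrays (0.43, adjusted p = 0.0837). The sizes for Ddx4 were uncertain, as its WT means (3.85, 3.34 and 3.13) lay under the arrays' lower quartiles.

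The rise of the imprinted gene Mest at d4 prompted the hypothesis, made after seeing the data, that imprinted genes rose as a set upon loss of Lsd1. The test was undecided: of 24 measured imprinted genes without Mest, 6 rose and 2 fell at d4 (median 0.07, camera adjusted p = 0.202). Ndn (1.22), Gatm (0.64) and Phlda2 (0.44) were among those higher.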
